A study of Mus musculus with 44 samples.

How the data were processed

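CD4 T cells purified from the spleens of NOD, NOR and C57BL/6 mice at 2, 3 and 4 weeks of age were measured on 44 Affymetrix mouse arrays, 1 per sample, with 45101 probe sets each. The 9 groups of strain and age follow the labels: 4 arrays for NOD at 2 weeks and 5 in each other group. The labels do not state that each sample came from a separate animal, so the p-values measure the spread between these samples. The number of arrays limits the precision.

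The deposited values are intensity on a linear scale, computed by the authors with MAS5, per the submitters' processing notes; its version is not given in the sources used here. Values ran from 0.1 to 90960.1, and the mean of each array without its lowest and highest 2% of probe sets was nearly the same in all 44. The table holds no detection calls. From these values log2(signal + 16) was computed, with no further scaling. Differences are on this scale, which understates the changes of genes with low signals, and a low signal does not show that a transcript is absent.

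Of the probe sets 34945 had 1 gene symbol, 932 several and 9160 none, and 64 control probe sets were left out. The Entrez identifiers of 34754 were found in a RefSeq table of the assembly GRCm38.p6, used only for gene names and gene order; 0 symbols were updated. A probe set was tested if its signal was above its own array's median in at least 4 of the 44 arrays, which kept 26880, among them 22422 with 1 symbol for 11977 genes and 4458 without exactly 1 symbol. Where a gene had several, the probe set with the highest mean stood for it in gene lists and named genes.

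One limma fit with a mean per group held all 44 arrays (35 residual degrees of freedom, 38.9 with the prior). Contrasts were the strain differences at each age and over the 3 ages with equal weight, 4 against 2 weeks in each strain, the difference of these age changes between NOD and each control, and an F test of the strain by age interaction. Calls needed a Benjamini-Hochberg adjusted p under 0.05, two-sided, over all probe sets tested in a contrast. A difference of NOD from both controls needed a call in the same direction in both. Its overlap was set against independent lists, against simulated unchanged groups with shared arrays, and against splits of the NOD arrays. The 39 gene lists, of T cell states, cell processes and other cell types, were tested with camera at a preset correlation of 0.01 and again with an estimated correlation. Whether called genes lie next to each other was tested by permuting calls among genes in chromosome order.

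Genes were named by a fixed rule. For the strain differences over ages, for NOD against both controls and for 4 against 2 weeks, these were the 10 largest rises and 10 largest falls past the threshold, with the same sign at all 3 ages for strain differences and ranked by the smaller of the differences for NOD against both. Within single ages and for differences of age changes they were the 5 largest each way. They needed 1 symbol; predicted and unnamed genes were counted but not named. The text gives only a part of the genes that the rule names, chosen after their values were seen, and genes left out can have changed by more than those given. Up to 4 passing members of each gene list were added. The groups, comparisons, tests, gene lists, naming rule and most alternatives were fixed before the data were examined; Itgal and the genes of the interaction test were named after their values were seen.

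Alternatives were the pseudocount, quantile normalization, median centring, the filter, 1 probe set per gene, a minimum fold of 1.5, only the arrays compared, the replicate number as a block, other eBayes settings, array weights, covariates for RNA integrity and for other cell types, and each array left out. Added after seeing the data were more cell type covariates, the fit without 1 NOR array, and classes of arrays by the signal of added poly-A controls relative to hybridisation controls, split within each age at the largest gap that leaves at least 4 arrays on each side; at 2 and 3 weeks a larger gap set 1 array apart. The tests were tested on simulated data with changes added to known probe sets. Noise was drawn independently for each probe set and array. The recovery and false calls therefore do not cover structure shared between the real arrays. Over the 3 ages, for NOD against NOR, 47.8% of changes of 0.5, 86.6% of changes of 1 and 100% of changes of 2 (log2) were recovered, with 8 false calls. At 2 weeks alone these were 7.5%, 41.8% and 90.9%, with 3 false calls. Software was R 4.3.3 with limma 3.58.1 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.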

Results

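RNA of CD4 T cells purified from spleen, neither cultured nor treated, was profiled on 44 arrays from 3 mouse strains. NOD mice develop autoimmune diabetes; NOR is a closely related strain that stays free of insulitis and diabetes and carries the same MHC haplotype; C57BL/6 resists diabetes and is more distant. Each strain had 5 arrays at 2, 3 and 4 weeks of age, except NOD at 2 weeks, which had 4. The median signal per array lay between 70.8 and 100.8, as scaled by the submitters. Cd4 measured 2780 ± 1020 (SD, n = 44) and the T cell receptor chain Cd3e 5030 ± 1450. For the CD8 chains, the brightest Cd8a probe set averaged 78.8 ± 36.1 and Cd8b1 220 ± 172, reaching 728 on 1 array; levels of different probe sets cannot be compared directly. Transcripts of other cells were abundant on the same arrays. The red cell carbonic anhydrases Car2 and Car1 measured 24200 ± 7430 and 18900 ± 6480, the granulocyte precursor enzyme Mpo 11100 ± 7750, the antibody joining chain Jchain 4000 ± 4350 and the B cell marker Ms4a1 729 ± 741. The labels do not give the sex of the mice. The brightest probe set of the X-linked Xist lay at 5680 or above on all 44 arrays. Among Y-linked genes, Eif2s3y averaged 27.6 and reached 655, Uty 15.7 and 256, and Kdm5d 17.3 and 200, by the probe set with the highest maximum. Other probe sets of these genes reached 29.4 to 191. Whether any sample holds RNA of both sexes was not tested.

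Which genes set NOD apart from both control strains was asked first. Trim12a and Trim12c, closely related members of the tripartite motif family, were nearly dark in NOD. Trim12a measured 6.91 ± 9.97 in NOD (SD, n = 14), 1460 ± 371 in NOR (n = 15) and 2119 ± 441 in C57BL/6 (n = 15), and Trim12c 5.14 ± 5.99, 1152 ± 307 and 1322 ± 294. The interferon-induced family member Trim30a was lower by a log2 difference of -2.07 ± 0.14 (SE) from NOR and -2.38 ± 0.14 from C57BL/6. Gatm, the first enzyme of creatine synthesis (-2.82 ± 0.17 and -2.49 ± 0.17), the carboxypeptidase Cpm (-2.28 ± 0.10 and -2.52 ± 0.10) and the complex I subunit Ndufs5 (-1.99 ± 0.09 and -2.83 ± 0.09) were also lower in NOD. Zfp979, a zinc finger protein, was higher in NOD at 1410 ± 359, against 131 ± 150 in NOR and 55.1 ± 43.8 in C57BL/6. Tmem87a (log2 3.48 ± 0.28 and 3.98 ± 0.28) and the stress-induced pseudokinase Trib3 (1.96 ± 0.16 and 1.23 ± 0.16) were higher as well.

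**Figure D1:**
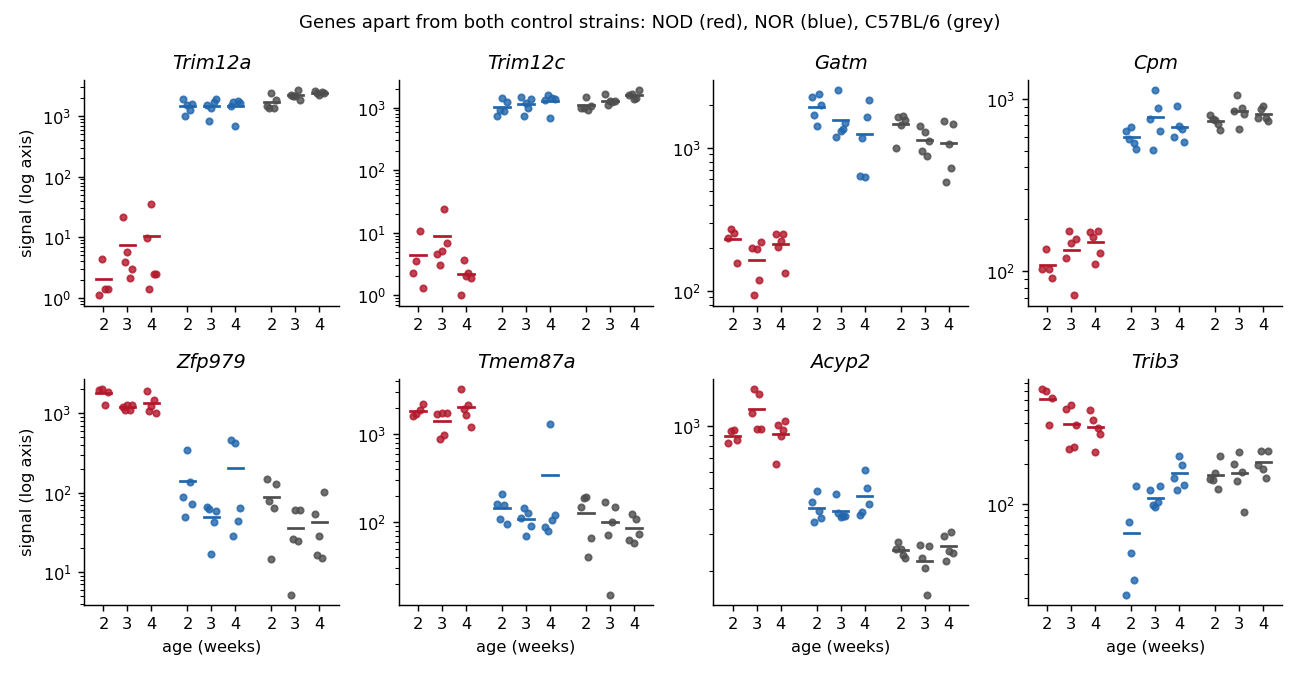
Signal per array on a log axis of 8 genes that differed between NOD (red) and both NOR (blue) and C57BL/6 (grey), by age in weeks; each point is 1 array and each line a group mean, with 4 arrays for NOD at 2 weeks and 5 in every other group. Trim12a lies between 1.1 and 35.9 in NOD and between 689.7 and 2704.5 in the control strains; 1 NOR array at 4 weeks has Tmem87a at 1306.8, within the range of NOD.

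The other genes named as higher in NOD than in both controls were Tcf15, Tmem98, the transfer RNA enzyme Thg1l, Ap1s3, Fhl3, Dnah2 and the acylphosphatase Acyp2, with log2 differences from NOR of 1.23 to 2.25. The others named as lower were Spata5l1, the aldo-keto reductase Akr1e1 and the zinc finger proteins Zfp593 and Zfp991, from -1.66 to -2.42. All 14 NOD arrays lay beyond all 30 control arrays for Zfp979, Acyp2, Trim12a, Trim12c, Gatm, Spata5l1, Cpm, Trim30a, Ndufs5, Zfp593 and Zfp991. A second probe set of Zfp991 was called the opposite way, and the second probe set of Trim12a was called only against C57BL/6. With limma, 339 probe sets of 220 named genes passed in the same direction against both controls over the 3 ages, 117 higher and 222 lower in NOD. At single ages 128 passed at 2 weeks, 178 at 3 weeks and 125 at 4 weeks.

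Both comparisons use the same NOD arrays. Independent lists of these sizes would share 27.7 higher and 38.5 lower probe sets. Unchanged groups simulated against shared arrays shared none in 100 draws. That simulation held no strain differences, so shared calls are rare in it by construction. It cannot tell how much overlap the shared arrays add between lists of the real sizes. With the NOD arrays split so that each control was compared with a different part of them, 20 splits gave 212 to 271 shared calls. The correlation of the differences across probe sets, which are not independent replicates, was below that of the simulation over the ages (0.328 against 0.524) and at 2, 3 and 4 weeks (0.354 against 0.578, 0.454 against 0.499 and 0.279 against 0.462), while their covariance over the ages was above it (0.0391 against 0.0148). A further 37 probe sets were called in opposite directions. With 5 lists of other cell types as covariates 127 probe sets passed over the ages, 85 at 3 weeks and 39 at 4 weeks.

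NOD was then set against NOR, the closer relative. Besides the genes above, Zzef1 was higher in NOD by a log2 difference of 2.52 ± 0.19 (SE; 14 NOD and 15 NOR arrays), as were Zfp937 (1.89 ± 0.22) and the neurofilament gene Nefh (1.79 ± 0.16). Wscd1 (-3.01 ± 0.21) and Cdk5rap1 (-2.12 ± 0.11) were lower; for Wscd1 and Cdk5rap1 the C57BL/6 signals, 14.5 ± 17.1 and 628 ± 135, stood near those of NOD, 6.02 ± 4.17 and 620 ± 76.9, and NOR measured 199 ± 154 and 2806 ± 548. Itgae, an integrin of tissue-resident lymphocytes, was higher by 0.95 ± 0.19 and Itgal lower by -0.50 ± 0.10.

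Over the 3 ages 528 of 26880 probe sets passed between NOD and NOR, 184 higher and 344 lower in NOD. The counts were 203 at 2 weeks (77 higher, 126 lower), 238 at 3 weeks (89 and 149) and 165 at 4 weeks (42 and 123). The 5 largest differences each way were nearly the same genes at each age, with Xaf1, an interferon-induced gene, among them only at 4 weeks (1.64 ± 0.36, adjusted p = 0.0124; a second probe set was called the opposite way). Its signal was higher in NOD at each age, and by the largest ratio at 2 weeks (715 ± 158 against 127 ± 73.4 in NOR, SD, n = 4 and 5). At 4 weeks Xaf1 missed the threshold without replicate 1 of NOD (adjusted p = 0.0555) and without replicate 1 or 5 of NOR (0.112 and 0.0543). Genes called between NOD and NOR lay next to each other on the chromosomes. Of 244 called genes 43 (17.6%) had a called gene as the next gene tested, against a mean of 2% and at most 5.7% in 10000 permutations of the calls (p = 0.0001, the smallest these permutations can give). The same share was 32.8% against 27.9% by chance for NOD against C57BL/6 and 32.3% against 27.2% for NOR against C57BL/6 (permutation p = 0.0001 for both, the smallest possible).

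**Figure D2:**
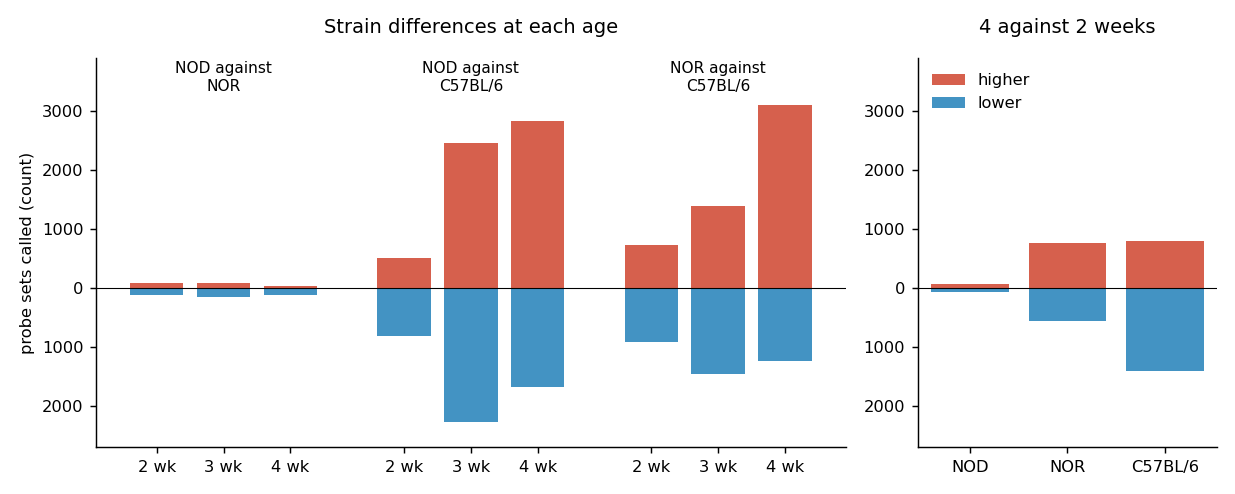
Number of probe sets called by limma at adjusted p under 0.05, drawn upwards where the first-named strain or age was higher (red) and downwards where it was lower (blue), for the strain differences at each age (left) and for 4 against 2 weeks in each strain (right). NOD and NOR differ at 203, 238 and 165 probe sets, and NOD and C57BL/6 at 1326, 4737 and 4519.

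Replicate 3 of NOR at 4 weeks stood between the strains at these genes. On a scale with the other NOR arrays at 0 and the NOD arrays at 1, its median position was 0.51 over genes higher in NOD and 0.65 over genes lower in NOD. The other 14 NOR arrays reached at most 0.04 and 0.35. For those at 4 weeks the reference included replicate 3, which moves their positions down. Medians do not cover single genes: replicate 1 of this group, at -0.07 and -0.02, had Akr1e1 at 30.1 and Ap1s3 at 848. Both lay within the range of NOD (9.3 to 146.6 and 651.1 to 1308). Its Tmem87a, Tmem98 and Fhl3 were the highest of its group, and its Trim12a and Trim12c the lowest. Without it, 187 probe sets passed at 4 weeks and 527 over the ages.

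**Figure D3:**
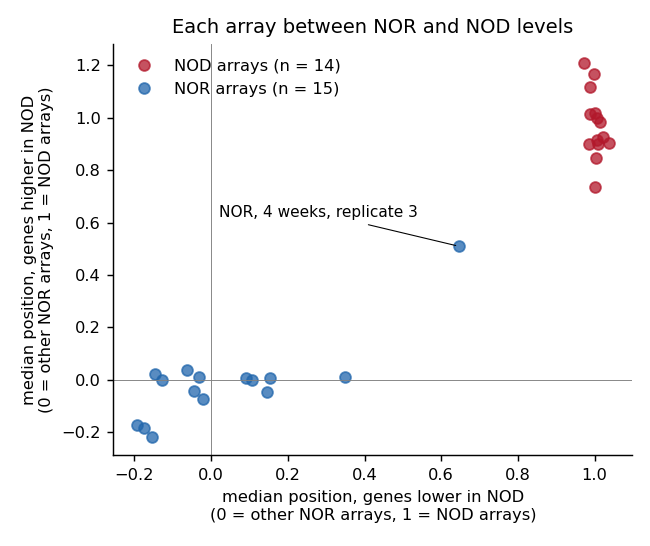
Median position of each NOR (blue, n = 15) and NOD (red, n = 14) array between the mean of the other NOR arrays (0) and the NOD arrays (1) of its age, over genes lower in NOD (horizontal axis) and higher in NOD (vertical axis). Replicate 3 of NOR at 4 weeks lies at 0.65 and 0.51.

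Interferon-induced genes were lower in NOD than in NOR. Of 29 measured type I interferon genes 8 were lower and 2 higher, 19 lower and 2 higher adjusted over the list alone, with a median log2 difference of -0.32. Trim30a, Ifit1 (-0.89 ± 0.13) and Ifit3 (-0.64 ± 0.10) were among those lower, and Xaf1 was higher (1.70 ± 0.22). The difference passed camera (adjusted p = 4.94e-17) and also with an estimated correlation (adjusted p = 0.000904). Of 16 interferon gamma induced GTPases and guanylate binding proteins 4 were lower, 9 adjusted over the list alone, with a median of -0.29. Iigp1 (-0.90 ± 0.14), Irgm2 (-0.56 ± 0.11), Gbp3 (-0.49 ± 0.11) and Gbp2 (-0.43 ± 0.11) led it (adjusted p = 1.47e-10, and 0.0334 with an estimated correlation). By age the median of the type I interferon list was -0.18 at 2 weeks (adjusted p = 0.417 with an estimated correlation), -0.33 at 3 weeks (0.00376) and -0.44 at 4 weeks (0.00308).

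Monocyte and macrophage genes were lower beside the interferon genes. Of 18 measured 4 were lower in NOD than in NOR (10 adjusted over the list alone), with a median of -0.49, among them the complement gene C1qc (-1.03 ± 0.26) and the growth factor receptor Csf1r (-0.91 ± 0.20). The adjusted p was 2.49e-10, and 0.182 with an estimated correlation. Haematopoietic progenitor and mast cell genes had a median of -0.15 with 2 of 11 lower, including the basophil protease Mcpt8 (-0.92 ± 0.25), and cytosolic ribosomal protein genes one of -0.18 with none of 36 called. The ribosomal call ended with quantile normalization, where the median was 0.01. The lists of CD8 T and NK cells (-0.19), MHC region antigen presentation (-0.15), B cells (0.21), Th1 genes (-0.14), dendritic cells (-0.13), diabetes locus candidates (-0.11) and T follicular helper genes (-0.10) also passed camera. With the monocyte list as a covariate the medians turned to 0.001 for Th1, 0.039 for T follicular helper, 0.02 for CD8 T and NK and 0.107 for dendritic cell genes. None of these 10 lists passed with an estimated correlation (adjusted p from 0.182 to 0.746).

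The other 27 lists did not pass between NOD and NOR. Among lists of T cells, the medians were 0.06 for CD4 identity, 0.02 for naive and quiescent cells, 0.01 for thymocytes and recent emigrants, 0.08 for activation and immediate early genes, -0.08 for regulatory T cells, -0.10 for Th2, -0.17 for Th17, 0.07 for T cell receptor signalling, 0.03 for common gamma chain cytokine signalling, -0.05 for NF-kappaB targets and -0.07 for chemokine receptors and trafficking. Among lists of cell processes they were 0.01 for the cell cycle, -0.01 for the unfolded protein response, 0.08 for heat shock, -0.04 for the antioxidant response, -0.04 for oxidative phosphorylation, -0.04 for glycolysis, -0.02 for fatty acid oxidation, -0.02 for cholesterol synthesis, 0.06 for ribosome biogenesis, 0.00 for the proteasome and 0.00 for apoptosis regulators. Plasma cell genes had 0.15, neutrophil and granulocyte precursor genes -0.14, erythroid genes 0.07, megakaryocyte and platelet genes -0.08 and stroma and endothelium genes -0.09.

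NOD and NOR were each set against C57BL/6, the more distant strain. Ccnb1ip1, a regulator of cyclin B and of meiotic recombination, measured 2083 ± 736 in NOD (SD, n = 14), 1846 ± 720 in NOR (n = 15) and 16.1 ± 17.7 in C57BL/6 (n = 15). The Ly49 family gene Klra16 (log2 5.56 ± 0.26 in NOD and 5.38 ± 0.25 in NOR), the pro-apoptotic gene Pawr (5.38 ± 0.14 and 5.31 ± 0.14), the sialyltransferase St6galnac2 (5.26 ± 0.13 and 5.05 ± 0.13) and the herpesvirus entry mediator Tnfrsf14 (4.00 ± 0.23 and 4.15 ± 0.22) were higher in both strains than in C57BL/6. The interferon-induced gene Ifi213 (-4.10 ± 0.15 and -4.11 ± 0.15), the lipid carrier Apoe (-3.87 ± 0.19 and -3.40 ± 0.19), the motor protein Myo6 (-3.15 ± 0.12 and -3.30 ± 0.11) and Tmem14c, a mitochondrial protein of haem synthesis (-3.05 ± 0.17 and -2.87 ± 0.17), were lower in both. Mir1931, Zfp874a and the fetal plasma protein Afp were also lower in both strains, by log2 differences of -3.04 to -4.81. Cttnbp2 was higher in both, by 3.26 ± 0.19 and 3.22 ± 0.18. Col6a4 and the potassium channel Kcnf1 were named as higher in NOD and the elastase Cela1 as lower, with differences of 3.18 ± 0.19, 3.04 ± 0.18 and -2.87 ± 0.13. Ear3, the interferon-induced Ifi202b, the class Ib MHC gene H2-T18 and the receptor kinase Mst1r were named as higher in NOR (2.86 to 3.43) and G0s2 and the drug transporter Abcb1b as lower (-2.79 and -2.77).

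Over the ages 7061 probe sets differed between NOD and C57BL/6, 4053 higher and 3008 lower, and 6838 between NOR and C57BL/6, 3976 higher and 2862 lower. At 2, 3 and 4 weeks the counts were 1326, 4737 and 4519 for NOD and 1643, 2851 and 4340 for NOR. At 4 weeks 2841 were higher and 1678 lower in NOD, and 3105 higher and 1235 lower in NOR. With each array centred on its median these became 1796 and 2459 in NOD and 1873 and 2237 in NOR, and with quantile normalization 2169 and 1615 in NOR. With lists of 5 other cell types as covariates 1192 probe sets differed for NOD and 798 for NOR. Without replicate 2 of C57BL/6 at 4 weeks 2872 probe sets differed between NOR and C57BL/6 at that age.

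Red cell and cell cycle genes were higher in both strains than in C57BL/6. Of 19 erythroid genes 17 were higher in NOD (17 adjusted over the list alone) and 16 in NOR (18 adjusted over the list alone), with medians of 0.82 for each strain. The anion exchanger Slc4a1 (1.85 ± 0.25 and 1.65 ± 0.25) and the haem enzyme Alas2 (1.61 ± 0.24 and 1.51 ± 0.24) led them. Of 37 cell cycle genes 30 were higher in NOD and 29 in NOR (34 each adjusted over the list alone), with medians of 0.51 and 0.44. These included the replication factor Cdc6 (0.94 ± 0.14 and 0.85 ± 0.13) and thymidylate synthase Tyms (0.82 ± 0.16 and 0.84 ± 0.16). Erythroid and cell cycle lists passed camera at adjusted p of 3.58e-10 and 2.71e-13 in NOD, and had adjusted p = 0.318 with an estimated correlation; in NOR it was 0.204 and 0.233. With the erythroid list as a covariate the cell cycle medians were 0.06 in NOD and 0.07 in NOR.

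**Figure D4:**
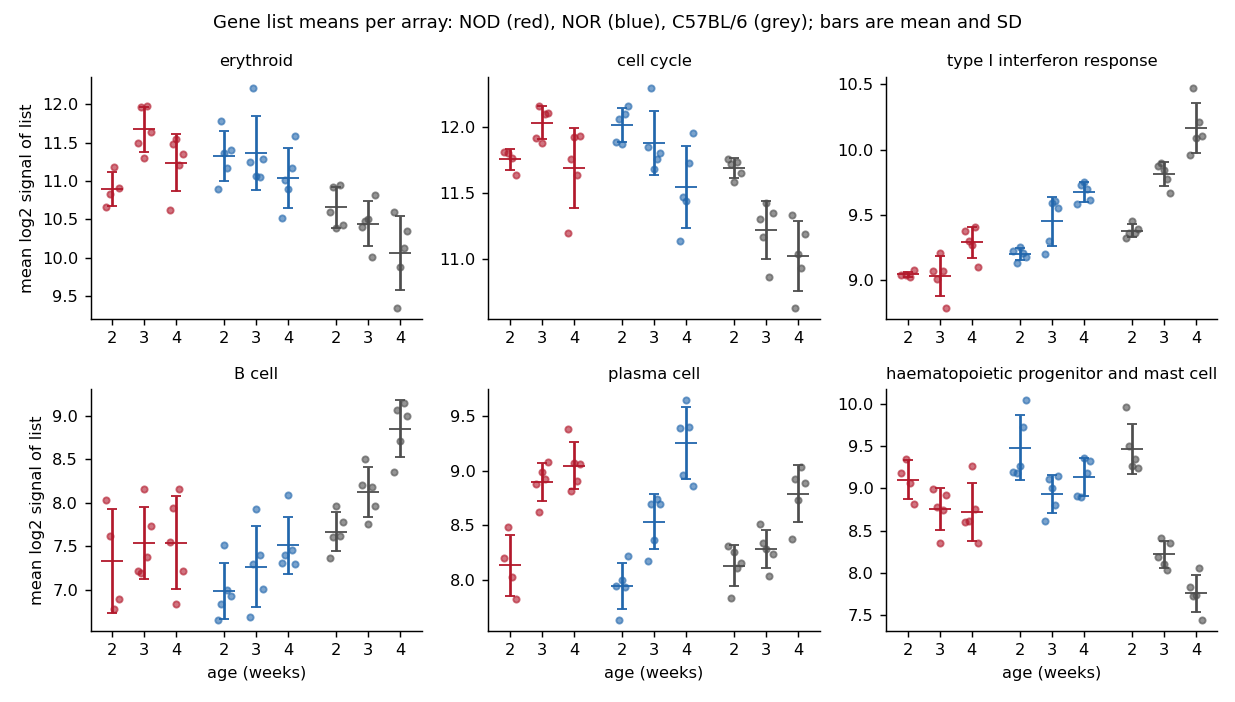
Mean log2 signal of 6 gene lists per array (points) by strain (NOD red, NOR blue, C57BL/6 grey) and age in weeks, with the group mean and SD as bars. The type I interferon list averages 9.04 in NOD, 9.20 in NOR and 9.38 in C57BL/6 at 2 weeks, and 9.29, 9.67 and 10.17 at 4 weeks.

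Type I interferon genes were lower in NOD than in C57BL/6 too. Of the 29, 23 were lower and 1 higher (25 and 1 adjusted over the list alone), with a median of -0.54, led by Trim30a, the antiviral gene Rsad2 (-1.51 ± 0.13), the oligoadenylate synthetase Oas1a (-1.44 ± 0.11) and Ifit1 (-1.30 ± 0.13). Adjusted p was 3.29e-14, and 0.0032 with an estimated correlation. In NOR 14 were lower and 2 higher (16 and 2 adjusted over the list alone), with a median of -0.30 and adjusted p = 0.204 with an estimated correlation. The NOR call was also lost with the erythroid list as a covariate, where the median was -0.09. The interferon gamma induced list had a median of -0.21 in NOD, with 4 of 16 lower, among them the peptide transporter Tap1 (-1.40 ± 0.16). It turned to 0.01 with the erythroid covariate, and its adjusted p was 0.659 with an estimated correlation.

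Markers of B cells were lower in both strains than in C57BL/6, with medians of -0.66 in NOD and -0.85 in NOR and 11 and 13 of 17 genes lower (12 and 13 adjusted over the list alone, and 1 higher in NOR), among them Ms4a1 (-1.73 ± 0.25 and -2.19 ± 0.24) and Cd72 (-1.79 ± 0.13 in NOD). Monocyte and macrophage genes were higher, with medians of 0.48 and 1.07 and 11 and 17 of 18 genes higher (the same numbers adjusted over the list alone), among them the lectin Lgals3 (1.67 ± 0.16 and 1.89 ± 0.16). Naive and quiescent T cell genes were lower, with medians of -0.40 and -0.49 and 9 and 11 of 19 genes lower (15 each adjusted over the list alone), among them Actn1 (-1.38 ± 0.12 and -1.53 ± 0.12) and the egress receptor S1pr1 (-0.63 ± 0.13 and -0.62 ± 0.12). The lists of MHC region antigen presentation (-0.47 and -0.35), T cell receptor signalling (-0.23 and -0.29) and CD4 T cell identity (-0.28 and -0.30) were lower as well. Antioxidant (0.17 and 0.28) and neutrophil and granulocyte precursor genes (0.67 and 0.36) were higher in both strains; the neutrophil list in NOR turned to -0.615 with the monocyte list as a covariate. Ribosomal protein genes (-0.15) passed in NOD, and progenitor and mast cell (0.68) and Th17 genes (0.37) in NOR. None of these calls held with an estimated correlation (adjusted p from 0.204 to 0.76). With the erythroid list as a covariate CD4 identity turned to 0.17 and 0.13, T cell receptor signalling to 0.09 and 0.02, and the antioxidant list to -0.08 in NOD; the naive list lost its call in both (-0.04 and -0.11), and so did the MHC list (-0.15 and -0.07).

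Changes between 2 and 4 weeks were followed within each strain. Antibody genes rose in all 3 strains. Igha, the constant chain of IgA, went from 123 ± 81.4 (SD, n = 4) to 4100 ± 1680 (n = 5) in NOD, from 214 ± 151 to 6660 ± 3400 in NOR and from 113 ± 32.9 to 968 ± 337 in C57BL/6. Of 33 immunoglobulin and joining chain probe sets 22 rose in NOD, 29 in NOR and 19 in C57BL/6, and none fell. Jchain rose by log2 3.71 ± 0.48 in NOD, 4.55 ± 0.46 in NOR and 2.95 ± 0.46 in C57BL/6. The plasma cell list had medians of 0.38 in NOD, 0.65 in NOR and 0.24 in C57BL/6, with adjusted p = 0.0271, 0.013 and 0.128 with an estimated correlation. Without these antibody genes 107 probe sets changed in NOD.

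Mpo, a granule enzyme of myeloid precursors, fell in all 3 strains. Its signal went from 19400 ± 3200 to 6350 ± 2550 in NOD, from 23400 ± 7260 to 11000 ± 2170 in NOR and from 19100 ± 3480 to 2340 ± 634 in C57BL/6 (n as above). The neutrophil list had a median of -1.41 in NOD with 3 of 15 lower (adjusted p = 0.218 with an estimated correlation), and medians of 0.14 in NOR and 0.11 in C57BL/6 (0.816 and 0.352). The arginase Arg1 fell in all 3 strains, and Stfa2l1 in NOD (-3.77 ± 0.53) and NOR (-2.235 ± 0.50). Stfa3 fell in NOD and NOR, where it missed the threshold without replicate 4 at 2 or at 4 weeks (adjusted p = 0.0845 and 0.0582). Haptoglobin (Hp) fell in C57BL/6 (-2.63 ± 0.36) and in NOD (-1.95 ± 0.38, with adjusted p = 0.0504 without replicate 2 at 2 weeks), and in NOR missed the threshold (-1.05 ± 0.36, adjusted p = 0.0768). The mast cell protease Mcpt4 fell in NOR (-2.28 ± 0.45) and C57BL/6 (-2.59 ± 0.45), and Tpsb2 was called in NOR alone (-2.91 ± 0.60). In C57BL/6 10 of 11 progenitor and mast cell genes fell (11 adjusted over the list alone), with a median of -1.54, among them Mcpt8 (-2.91 ± 0.43), the stem cell antigen Cd34 (-2.64 ± 0.25) and the histamine enzyme Hdc (-2.41 ± 0.35). That list held with an estimated correlation (adjusted p = 0.000384). Mcpt8 turned to 0.48 with 5 cell type lists as covariates, but this list, with Mcpt8 as a member, is 1 of the 5. In NOD the list had a median of -0.08 and in NOR of -0.24, with adjusted p = 0.515 and 0.338 with an estimated correlation.

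Type I interferon genes rose between 2 and 4 weeks in C57BL/6 and NOR. In NOD they had the smallest median and passed camera only at the preset correlation. In C57BL/6 21 of 29 rose and none fell (24 adjusted over the list alone), with a median of 0.79, among them Ifi27l2a (1.72 ± 0.21) and the deubiquitinase Usp18 (1.44 ± 0.18). In NOR 9 rose and none fell (15 adjusted over the list alone), with a median of 0.50, among them Oas2 (0.90 ± 0.20) and Mx1 (0.89 ± 0.21). Both held with an estimated correlation (adjusted p = 0.000197 and 0.0143). In NOD the median was 0.21 and none of 29 passed (2 rose adjusted over the list alone). The list passed camera in NOD (adjusted p = 1.81e-05), but not with an estimated correlation (0.218) nor with the spike-in class as a block. Lists of cell makeup moved beside these genes: the medians in C57BL/6, NOR and NOD were 0.45, 0.46 and 0.06 for CD4 T cell identity, -0.62, -0.35 and 0.36 for erythroid genes, and 0.69, 0.21 and 0.32 for CD8 T and NK cells. With an estimated correlation none of these 3 lists passed in any strain (adjusted p from 0.298 to 0.934 in NOR and NOD, and 0.199, 0.328 and 0.308 in C57BL/6). The interferon gamma induced list rose by medians of 0.75 in C57BL/6 and 0.53 in NOR (0.0131 and 0.0604 with an estimated correlation). Cell cycle genes fell by medians of 0.67 in C57BL/6, with 22 of 37 lower, and 0.46 in NOR, with 10 of 37 lower (adjusted p = 0.0959 and 0.239 with an estimated correlation), and their median in NOD was -0.06. B cell genes rose in C57BL/6 by a median of 1.096, with 11 of 17 higher, among them Fcer2a (2.27 ± 0.44) and Cr2 (2.25 ± 0.41) (adjusted p = 0.0806 with an estimated correlation).

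In NOD 129 probe sets changed with age (64 higher, 65 lower), in NOR 1321 (768 and 553) and in C57BL/6 2204 (799 and 1405). Centring on the median gave 509 higher and 836 lower in NOR and 1063 and 877 in C57BL/6, and quantile normalization 631 and 690 in NOR. Of 39 lists 13 passed camera in NOD, 28 in NOR and 26 in C57BL/6, and 1, 2 and 3 with an estimated correlation. A technical measure moved with age: the added poly-A controls minus the hybridisation controls averaged -5.42 log2 units at 2 weeks, -3.57 at 3 weeks and -2.13 at 4 weeks. Arrays were then split at each age into a low and a high class of this measure. With the class as a block 3435 probe sets changed in NOD, 6167 in NOR and 6830 in C57BL/6. Within the low class alone the counts were 1482, 3258 and 5160, and within the high class 906 in NOR and 3641 in C57BL/6. The classes were cut separately at each age, with the low class reaching up to -5.88 at 2 weeks and -3.14 at 4 weeks. These age changes, with the block or within a class, therefore compare arrays at different levels of the measure. They do not remove its shift with age. NOD at 4 weeks had 1 array in the high class, so its age change within that class rests on that array and tells nothing. With the 5 cell type lists as covariates 76, 293 and 2 probe sets changed. The NOD count was 83 without its replicate 2 at 2 weeks. The NOR count was 449 and 754 without replicates 4 and 5 at 2 weeks, and 396 and 830 without replicates 1 and 3 at 4 weeks. The C57BL/6 count was 1410 without replicate 2 at 2 weeks and 1163 without replicate 2 at 4 weeks.

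Whether the age change differed between strains was tested directly. Cd34 fell less in NOD than in C57BL/6, with a difference of log2 1.94 ± 0.36 (SE, adjusted p = 0.0291), and so did the receptor Adgrg3 (1.26 ± 0.25). The glycosyltransferase Gcnt2 changed by -1.295 in C57BL/6 and by 0.056 in NOD, a difference of 1.35 ± 0.25. Zfp120 differed by -1.60 ± 0.31. Cd34 missed the threshold without replicates 1, 2 or 4 of NOD or 1 or 2 of C57BL/6 at 2 weeks. It also did so without 2 or 3 of NOD or 2 or 5 of C57BL/6 at 4 weeks. In these fits its adjusted p ran from 0.0519 to 0.0897 and its difference from 1.77 to 1.96. Gcnt2, Adgrg3 and Zfp120 missed the threshold without most of these arrays. Adgrg3 and Zfp120 also did so without replicate 5 of NOD at 4 weeks, and Adgrg3 without its replicate 4 (adjusted p from 0.0535 to 0.115 for these genes). The type I interferon list rose less in NOD than in C57BL/6 (median -0.60, adjusted p = 0.011 with an estimated correlation), with no single member past the threshold, and the progenitor and mast cell list fell less (1.29, adjusted p = 0.00507 with an estimated correlation). Between NOD and NOR the type I interferon list had a median of -0.23 (adjusted p = 0.271 with an estimated correlation). Apart from the estimated correlation, these list differences were not run under the alternatives, with arrays left out or in other splits. Whether they depend on the processing or on few arrays was therefore not tested.

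Over the 3 strains 18 probe sets had a strain by age interaction, among them those of adrenomedullin (Adm), the chromatin organiser Satb1, the IgM heavy chain Ighm, C1qa and the mast cell receptor chain Ms4a2. For the age change in NOD minus that in C57BL/6, 9 probe sets passed (6 higher and 3 lower), and 2 and 6 when each array was centred on its median. For NOD minus NOR limma called 0, with 1162 at an unadjusted p under 0.05, and 1 without replicate 5 of NOR at 2 weeks. The interaction count was 1382 with array weights, 385 with the monocyte list as a covariate, 220 with the spike-in class as a block, 63 with the Gapdh ratio as a covariate, 37 within the low class, 11 with median centring, 8 with the erythroid covariate or without the filter, 7 with 1 probe set per gene and 0 with 5 cell type lists as covariates. The count for NOD minus C57BL/6 was 2099, 48, 61 and 26 under the first 4 of these, 15 with a pseudocount of 64, 2 with the B cell and erythroid covariates, and 5 without the NOR array between the strains. It was 0 with quantile normalization, without the filter, with the erythroid or the 5 cell type covariates, within either class and with only the arrays compared. Both counts also turned on few arrays. Without replicate 1 of C57BL/6 at 4 weeks the interaction count was 289, and it was 28 without replicate 5 of NOR at 2 weeks. It was 5 to 11 without replicates 1, 2 and 3 of C57BL/6 at 2 weeks, 2 and 5 at 3 weeks and 2 and 4 at 4 weeks, or replicate 4 of NOD at 3 weeks and 2, 4 and 5 at 4 weeks. The count for NOD minus C57BL/6 was 104 without replicate 1 of C57BL/6 at 4 weeks and 44 without replicate 1 of NOD at 4 weeks. It was 0 to 3 without replicates 1, 2 and 4 of NOD at 2 weeks and 2, 3 and 5 at 4 weeks, or replicates 1 and 2 of C57BL/6 at 2 weeks and 2 and 5 at 4 weeks.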

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

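The tests of B cell and monocyte genes against C57BL/6 and those using the spike-in class, the 5 cell type covariates or the monocyte or erythroid covariate alone were chosen only after the result was seen. In this section the SE of a list median is taken over the genes of the list, as if they were independent. It does not measure the spread between arrays, so what is argued with it leaves that spread out.

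Erythroid and cell cycle genes were higher in NOD and NOR than in C57BL/6, but neither list passed with an estimated correlation (adjusted p = 0.318 for both in NOD, 0.204 and 0.233 in NOR). A lower share of T cells that raises all other cell types alike is argued against. The B cell list was lower in NOD, with a median of -0.664 (SE 0.201), while the erythroid list was higher at 0.82. A lower share of T cells with unequal changes of the other cells stays open. CD4 T cell identity had medians of -0.284 in NOD and -0.296 in NOR, and of 0.171 and 0.133 with the erythroid list as a covariate. A processing batch that follows the spike-in class is argued against as well, since the erythroid median was 0.856 (SE 0.112) with the class as a block. Batches not seen in the spike-in controls were not tested. The cell cycle median fell from 0.511 to 0.061 (SE 0.036) with the erythroid list as a covariate, so dividing red cell precursors in the preparations may account for the cell cycle difference. A difference between the strains in these cells stays open and was not tested.

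Type I interferon genes were lower in NOD than in both controls. Fewer monocytes and macrophages are argued against as the whole cause, since the median against NOR was -0.318 (SE 0.14) with the monocyte list as a covariate, from -0.317, and the monocyte list was higher in NOD than in C57BL/6, at 0.475 (SE 0.134). Of 17 other probe sets of these genes 15 were lower in NOD than in NOR, which argues against sequence differences under single probe sets as the whole cause. The exact binomial test (one-sided p = 0.00117) takes the probe sets as independent, which those of 1 gene are not. Sequence differences shared by the probe sets of a gene stay open. A processing batch that follows the spike-in class is argued against too, at -0.317 (SE 0.132) with the class as a block. Batches not seen in these controls were not tested. With 5 cell type lists as covariates (B cell, erythroid, monocyte, neutrophil and progenitor) the median was -0.36 against NOR, which argues against these cells as the whole cause there, and -0.328 against C57BL/6, from -0.542, where a part stays open. A lower interferon response in NOD cells is a candidate explanation, as a hypothesis found and tested on the same data, and cells outside these lists stay open.

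The largest strain differences sat at single genes such as Trim12a, Trim12c and Zfp979. Of 260 probe sets at least 4-fold different between NOD and C57BL/6, 190 were lower in NOD. The exact binomial test (one-sided p = 2.8e-14) takes these probe sets as independent. Probes made for the C57BL/6 sequence that lose signal in other strains would give this direction. Called genes of NOD against NOR lay next to each other in 17.6% of cases against 2% by chance (permutation p = 0.0001, the smallest possible), in line with blocks of the genome that differ between these strains. Whether probe sets or transcripts differ between NOD and NOR cannot be told apart, since 12 of 24 genes with another probe set had one called the same way (exact binomial test, one-sided p = 0.581). No sequence of the strains was analysed here, so lost probe binding may remain for any single gene.

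Single samples far from the rest of their group were found in 24 of 288 groups over 32 quantities, and chance gives about 14.4. Gene and list values here are log2(signal + 16). In NOR at 3 weeks, replicate 2 had an erythroid mean of 12.21 (the others 11.05 to 11.29), a cell cycle mean of 12.3 (11.68 to 11.85) and Tmem98 at 7.508 (6.844 to 6.974), and replicate 1 had Acyp2 at 8.925 (8.566 to 8.629). In NOR at 4 weeks, replicate 3 had a B cell mean of 8.093 (7.295 to 7.452), Tmem87a at 10.37 (6.588 to 7.107), Tmem98 at 9.316 (7.171 to 7.516), Fhl3 at 6.425 (4.517 to 4.916), Trim12a at 9.463 (10.55 to 10.83) and Trim12c at 9.434 (10.4 to 10.64). Replicate 1 of that group had Tcf15 at 4.678 (6.55 to 7.061) and Akr1e1 at 5.527 (8.162 to 9.072). In NOD at 4 weeks, replicate 1 had a poly-A minus hybridisation control signal of 0.2145 (-4.457 to -3.135) and Tmem98 at 8.4 (9.091 to 9.239). Replicate 3 of that group had Thg1l at 9.748 (9.287 to 9.394), and replicate 4 Akr1e1 at 4.661 (6.066 to 6.397). In NOD at 3 weeks, replicate 5 had a median signal of 88.8 (79.2 to 81.4) and Dnah2 at 7.417 (6.5 to 6.766), replicate 1 Trim12a at 5.244 (4.178 to 4.44) and replicate 4 Trim12c at 5.322 (4.248 to 4.517). In NOD at 2 weeks, replicate 3 had Zfp979 at 10.33 (10.88 to 10.98) and replicate 2 Trim12a at 4.343 (4.096 to 4.121). In C57BL/6 at 2 weeks, replicate 4 had Thg1l at 6.952 (8.017 to 8.391) and replicate 1 Gatm at 9.993 (10.52 to 10.72).

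The change from 2 to 4 weeks differed between NOD and C57BL/6 by 1.939 for Cd34 (adjusted p = 0.0291), 1.351 for Gcnt2 (0.0291), 1.261 for Adgrg3 (0.0412) and -1.597 for Zfp120 (0.0412). The medians of these differences were -0.604 for the type I interferon list and 1.292 for the haematopoietic progenitor and mast cell list, both past the threshold with an estimated correlation (0.011 and 0.00507). These 2 list results were not run under the other alternatives, with arrays left out or in other splits.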

How the results depend on the processing

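The alternatives on the spike-in class, its low and high class, the 5 cell type lists, the monocyte and erythroid covariates and the NOR array left out were chosen after seeing the data. Counts are of probe sets called by limma, given where they moved by over 1.5 times. Where no cause is named, the cause was not tested. The lower type I interferon median in NOD kept its direction and its side of the threshold under 15 alternatives, from -0.36 to -0.284 against NOR and from -0.628 to -0.328 against C57BL/6, and so did the interferon gamma induced list against NOR (-0.36 to -0.224). The same held for the rise of the type I interferon list between 2 and 4 weeks in NOR (0.313 to 0.506) and C57BL/6 (0.502 to 0.866). With an estimated correlation the lists called became 2, 1 and 0 for the 3 strain differences over ages (NOD against NOR, NOD against C57BL/6, NOR against C57BL/6) and 1, 2 and 3 for the age changes in NOD, NOR and C57BL/6. Over all named genes and single arrays left out, 3883 results stayed on their side of the threshold, 51 lost their call and 0 reversed. The named genes were picked as the largest passing differences in these same arrays, so this says little about other calls. With group means taken out, samples of different strains with the same replicate number had mean correlations of -0.004 at 2 weeks and 0.014 at 3 weeks. Samples with different numbers had 0 and -0.003, so the numbers showed no pairing there. At 4 weeks the means were 0.144 and -0.035, with 8 of 15 and 19 of 60 pairs above 0.1. Replicate 1 was in the high spike-in class in all 3 strains at that age, and replicates 2 and 3 in the low class. A structure shared by replicate number at 4 weeks is not excluded. With the replicate block NOD and NOR differed at 538 probe sets over ages and NOD from both controls at 352, no count of probe sets or lists moved by over 1.5 times, and 3 list calls crossed the threshold. The proteasome list gained a call for NOD against C57BL/6 over ages (0.102) and for 4 against 2 weeks in NOD (-0.149), and the neutrophil and granulocyte precursor list lost its call for NOD against C57BL/6 over ages (0.673). The tables hold no detection calls, so at low signal a transcript near background is not told apart from one that is absent.

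With a pseudocount of 64 the counts were 15 for the age change in NOD minus that in C57BL/6. With quantile normalization the counts were 0 for the age change in NOD minus that in C57BL/6. Lists that turned direction in camera had medians, for NOD against NOR over ages, of cytosolic ribosomal proteins 0.008. In the case of 4 against 2 weeks in NOD these were cytosolic ribosomal proteins -0.012. In the case of 4 against 2 weeks in NOR these were cytosolic ribosomal proteins 0.014. With arrays centred on their median the counts were 11 for the strain by age interaction. Without the filter on low values, which tests more probe sets, the counts were 856 in NOR for 4 against 2 weeks, 8 for the strain by age interaction, 0 for the age change in NOD minus that in C57BL/6. With 1 probe set per gene, which tests fewer of them, the counts were 82 at 2 weeks, 109 at 3 weeks, 75 at 4 weeks and 257 over ages for NOD against NOR, 575 at 2 weeks, 2688 at 3 weeks, 2106 at 4 weeks and 3476 over ages for NOD against C57BL/6, 758 at 2 weeks, 1578 at 3 weeks, 1689 at 4 weeks and 3390 over ages for NOR against C57BL/6, 53 at 2 weeks, 79 at 3 weeks, 58 at 4 weeks and 157 over ages for NOD against both controls, 77 in NOD, 790 in NOR and 1418 in C57BL/6 for 4 against 2 weeks, 7 for the strain by age interaction. With a fold of at least 1.5 required the counts were 3051 over ages for NOD against C57BL/6, 2884 over ages for NOR against C57BL/6. With the Gapdh 3 prime to 5 prime ratio as a covariate the counts were 63 for the strain by age interaction, 26 for the age change in NOD minus that in C57BL/6. With the B cell and erythroid lists as covariates the counts were 1409 at 3 weeks, 1479 at 4 weeks and 2814 over ages for NOD against C57BL/6, 1446 at 3 weeks, 2308 at 4 weeks and 2719 over ages for NOR against C57BL/6, 579 in NOR and 356 in C57BL/6 for 4 against 2 weeks, 2 for the age change in NOD minus that in C57BL/6. The number of lists called became 10 for 4 against 2 weeks in C57BL/6. Lists that turned direction in camera had medians, for NOD against C57BL/6 over ages, of CD4 T cell identity 0.225, interferon gamma induced GTPases and guanylate binding proteins 0.117, antioxidant response -0.032 and T cell receptor signalling 0.111. For NOR against C57BL/6 over ages these were CD4 T cell identity 0.264, T cell receptor signalling 0.048 and MHC region antigen presentation 0.252. In the case of 4 against 2 weeks in C57BL/6 these were chemokine receptors and trafficking -0.15 and CD8 T and NK cell 0.118. With array weights the counts were 435 at 3 weeks for NOD against NOR, 2116 at 2 weeks, 7264 at 3 weeks and 8348 at 4 weeks for NOD against C57BL/6, 2718 at 2 weeks and 4299 at 3 weeks for NOR against C57BL/6, 296 at 3 weeks for NOD against both controls, 872 in NOD, 2092 in NOR and 5992 in C57BL/6 for 4 against 2 weeks, 1382 for the strain by age interaction, 2099 for the age change in NOD minus that in C57BL/6. With the spike-in class as a block the counts were 430 at 3 weeks for NOD against NOR, 301 at 3 weeks for NOD against both controls, 3435 in NOD, 6167 in NOR and 6830 in C57BL/6 for 4 against 2 weeks, 220 for the strain by age interaction, 61 for the age change in NOD minus that in C57BL/6. The number of lists called became 7 for 4 against 2 weeks in NOD. With 5 cell type lists as covariates the counts were 874 at 2 weeks, 859 at 3 weeks, 490 at 4 weeks and 1192 over ages for NOD against C57BL/6, 1044 at 2 weeks, 1131 at 3 weeks, 281 at 4 weeks and 798 over ages for NOR against C57BL/6, 85 at 3 weeks, 39 at 4 weeks and 127 over ages for NOD against both controls, 76 in NOD, 293 in NOR and 2 in C57BL/6 for 4 against 2 weeks, 0 for the strain by age interaction, 0 for the age change in NOD minus that in C57BL/6. The number of lists called became 5 for NOD against NOR over ages, 6 for NOD against C57BL/6 over ages, 0 for NOR against C57BL/6 over ages, 4 for 4 against 2 weeks in NOD, 14 for 4 against 2 weeks in NOR and 14 for 4 against 2 weeks in C57BL/6. Lists that turned direction in camera had medians, for NOD against NOR over ages, of CD8 T and NK cell 0.01 and dendritic cell -0.054. For NOD against C57BL/6 over ages these were CD4 T cell identity 0.605, cell cycle -0.065, interferon gamma induced GTPases and guanylate binding proteins 0.119 and T cell receptor signalling 0.119. For NOR against C57BL/6 over ages these were CD4 T cell identity 0.782, naive and quiescent T cell -0.064, cell cycle -0.05, T cell receptor signalling 0.128 and MHC region antigen presentation 0.44. In the case of 4 against 2 weeks in C57BL/6 these were CD4 T cell identity -0.016, naive and quiescent T cell -0.208, activation and immediate early response -0.562, T follicular helper and memory-like -0.084, apoptosis regulators -0.099, T cell receptor signalling -0.376, common gamma chain cytokine signalling -0.299, NF-kappaB targets -0.234, diabetes locus candidates -0.257 and megakaryocyte and platelet -0.157. For 4 against 2 weeks in C57BL/6, Igkv15-103 turned to -0.191 and Mcpt8 turned to 0.483. Mcpt8 is itself a member of 1 of the 5 lists. With the monocyte list as a covariate the counts were 5062 at 3 weeks for NOR against C57BL/6, 263 in NOD for 4 against 2 weeks, 385 for the strain by age interaction, 48 for the age change in NOD minus that in C57BL/6. The number of lists called became 6 for NOD against NOR over ages. Lists that turned direction in camera had medians, for NOD against NOR over ages, of Th1 0.001, T follicular helper and memory-like 0.039, CD8 T and NK cell 0.02 and dendritic cell 0.107. For NOR against C57BL/6 over ages these were neutrophil and granulocyte precursor -0.615. With the erythroid list as a covariate the counts were 1404 at 3 weeks, 2068 at 4 weeks and 3214 over ages for NOD against C57BL/6, 1522 at 3 weeks and 3448 over ages for NOR against C57BL/6, 882 in C57BL/6 for 4 against 2 weeks, 8 for the strain by age interaction, 0 for the age change in NOD minus that in C57BL/6. The number of lists called became 22 for 4 against 2 weeks in NOD. Lists that turned direction in camera had medians, for NOD against C57BL/6 over ages, of CD4 T cell identity 0.171, interferon gamma induced GTPases and guanylate binding proteins 0.014, antioxidant response -0.081 and T cell receptor signalling 0.091. For NOR against C57BL/6 over ages these were CD4 T cell identity 0.133 and T cell receptor signalling 0.018. Without the NOR array that lay between the strains the counts were 830 in NOR for 4 against 2 weeks, 5 for the age change in NOD minus that in C57BL/6. With only the arrays compared in the fit, so with fewer residual degrees of freedom, the counts were 109 at 2 weeks and 90 at 4 weeks for NOD against NOR, 2500 at 4 weeks for NOD against C57BL/6, 2493 at 4 weeks for NOR against C57BL/6, 77 at 4 weeks for NOD against both controls, 50 in NOD, 290 in NOR and 913 in C57BL/6 for 4 against 2 weeks, 0 for the age change in NOD minus that in C57BL/6. Within the low spike-in class, which holds fewer arrays, the counts were 130 at 2 weeks, 489 at 3 weeks and 64 at 4 weeks for NOD against NOR, 727 at 2 weeks for NOD against C57BL/6, 985 at 2 weeks and 2532 at 4 weeks for NOR against C57BL/6, 81 at 2 weeks, 365 at 3 weeks and 55 at 4 weeks for NOD against both controls, 1482 in NOD, 3258 in NOR and 5160 in C57BL/6 for 4 against 2 weeks, 37 for the strain by age interaction, 0 for the age change in NOD minus that in C57BL/6. Fewer arrays do not account for the counts that rose in this class or in the high class, and the cause of the rise was not tested. The classes were cut separately at each age. Age changes with the class as a block or within a class therefore compare arrays at different levels of the spike-in controls. Within the high spike-in class, which holds fewer arrays too, the counts were 88 at 2 weeks for NOD against NOR, 769 at 2 weeks, 534 at 3 weeks, 751 at 4 weeks and 2077 over ages for NOD against C57BL/6, 793 at 2 weeks and 1233 at 4 weeks for NOR against C57BL/6, 55 at 2 weeks for NOD against both controls, 1567 in NOD and 3641 in C57BL/6 for 4 against 2 weeks, 4 for the age change in NOD minus that in NOR, 0 for the age change in NOD minus that in C57BL/6. With genes counted as neighbours within the next 5 tested, the share for NOD against C57BL/6 was 80.2%, as by chance (80.2%), since most stretches of 5 genes then hold a called one. In the high class NOD at 4 weeks and C57BL/6 at 3 weeks had 1 array each. Counts for NOD against C57BL/6 at 3 weeks, at 4 weeks and over ages, for 4 against 2 weeks in NOD and for the age change in NOD minus that in either control rest on these arrays, with the spread taken from other groups. They tell nothing about whether those results hold. Within the high class no value could be had for contrasts with NOR at 3 weeks, which has no array in it, nor for NOD against NOR, NOR against C57BL/6 and NOD against both controls over the ages.

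With 1 array left out at a time, the count changed as follows. For NOD against NOR it ran from 159 to 202 at 2 weeks, 210 to 267 at 3 weeks, 130 to 187 at 4 weeks and 475 to 549 over ages. For NOD against C57BL/6 it ran from 1128 to 1274 at 2 weeks, 3606 to 4475 at 3 weeks, 3156 to 5295 at 4 weeks and 6448 to 7557 over ages. For NOR against C57BL/6 it ran from 1357 to 1598 at 2 weeks, 2022 to 2877 at 3 weeks, 2872 to 5433 at 4 weeks and 6238 to 7498 over ages. For NOD against both controls it ran from 109 to 127 at 2 weeks, 160 to 202 at 3 weeks, 100 to 136 at 4 weeks and 324 to 361 over ages. For 4 against 2 weeks it ran from 83 to 128 in NOD, 396 to 1801 in NOR and 1163 to 3260 in C57BL/6. For the strain by age interaction it ran from 5 to 289, for the age change in NOD minus that in NOR from 0 to 1, and for that in NOD minus C57BL/6 from 0 to 104.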

Other observations

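The test of the NOR array between the strains and the values with the spike-in class as a block were chosen only after the result was seen. Some genes of differentiated T cells rose between 2 and 4 weeks in the control strains, beside shifts of other lists. In NOR 6 of 16 T follicular helper and memory-like genes rose (13 adjusted over the list alone), with a median of 0.67, among them the inhibitory receptor Lag3 (1.85 ± 0.43, SE) and the transcription factor Bcl6 (0.83 ± 0.20), at adjusted p = 0.0506 with an estimated correlation. In NOR 5 of 20 regulatory T cell genes rose (10 adjusted over the list alone), with a median of 0.53, among them the ectoenzyme Nt5e (1.17 ± 0.21) and Ctla4 (0.87 ± 0.20), at adjusted p = 0.0798 with an estimated correlation. In C57BL/6 8 of 18 Th1 genes rose and 1 fell (12 and 1 adjusted over the list alone), with a median of 0.61, among them the granzyme Gzmk (1.67 ± 0.31) and the chemokine Ccl5 (1.62 ± 0.32), at adjusted p = 0.128 with an estimated correlation. In the same contrast the CD8 T and NK cell list had a median of 0.69, with 3 of 13 higher and 1 lower (adjusted p = 0.308 with an estimated correlation). CD4 T cell identity genes had medians of 0.45 in C57BL/6 and 0.46 in NOR (0.199 and 0.298), and erythroid genes -0.62 and -0.35 (0.328 and 0.492). None of these genes of the follicular helper, regulatory and Th1 lists was called between 2 and 4 weeks in NOD by limma, where the list medians were 0.15, 0.11 and 0.13; the age change in NOD minus that in NOR itself passed for no gene (0 by limma, 1162 at an unadjusted p under 0.05).

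Some metabolic genes changed between 2 and 4 weeks in NOR. Of 17 fatty acid oxidation genes 5 fell (7 adjusted over the list alone), with a median of -0.30, among them Hadh (-0.99 ± 0.22) and Cpt1a (-0.76 ± 0.15), which brings fatty acids into mitochondria. Of 18 cholesterol synthesis genes 4 rose, with a median of 0.37, among them Hmgcs1 (0.66 ± 0.16) and Cyp51 (0.59 ± 0.12). Neither list passed with an estimated correlation (adjusted p = 0.0604 and 0.0506). The oxidative phosphorylation list had a median of -0.27 with 4 of 45 lower (adjusted p = 0.298 with an estimated correlation), and glycolysis one of -0.06 with 0 of 18 called. In the same contrast the medians were 0.65 for plasma cell, -0.44 for megakaryocyte and -0.35 for erythroid genes, with adjusted p = 0.013, 0.298 and 0.492 with an estimated correlation. Igf2bp3, an RNA-binding protein of fetal blood cells, fell in all 3 strains, by -1.73 ± 0.20 in NOD, -1.61 ± 0.18 in NOR and -1.44 ± 0.18 in C57BL/6.

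Replicate 3 of NOR at 4 weeks lay between NOR and NOD, at 0.509 over genes higher in NOD and 0.647 over genes lower in NOD, against at most 0.348 for the other NOR arrays. A mixture of NOD and NOR transcripts in this sample is a candidate explanation. A mouse carrying alleles of both strains and RNA mixed from both would look alike in this test, and nothing here separates them.

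Other splits of the same arrays, 100 with the real one, were used to ask how often regrouping gives as many calls. A count was taken as uncommon where under 5 of the 100 splits gave as many, which does not exclude chance. Over the ages the counts were uncommon for NOD against NOR (528, highest other split 121) and NOD against C57BL/6 (7061 and 48). They were also uncommon for NOR against C57BL/6 (6838 and 130) and NOD against both controls (339 and 0). In each, 1 of the 100 splits, the real one, gave as many. At 4 weeks the count was uncommon for NOD against NOR, though another split came close (165 and 164). That split and the real one had the same gap between groups in the share of low spike-in class arrays (0.4). Counts were uncommon at 3 and 4 weeks for NOD against C57BL/6 (4737 and 762, 4519 and 2539). For NOR against C57BL/6 they were uncommon at 2, 3 and 4 weeks (1643 and 1033, 2851 and 1018, 4340 and 4387, the last with 2 splits as large). For NOD against both controls they were uncommon at each age (128 and 43, 178 and 245, 125 and 109, with 1, 2 and 1 splits). At 2 weeks they were uncommon for NOD against NOR (203) and NOD against C57BL/6 (1326), with 2 splits each. There the other split followed the spike-in class fully and gave 1258 and 2124. With the class as a block these counts were 283 and 1677. For NOD against NOR at 3 weeks 5 splits gave 238 or more, up to 1842, so this count was not uncommon. With the class as a block 430 passed. Splits that call several times the real count point to a structure of the arrays other than strain. With group means taken out, samples of 1 age and different strains had a mean correlation of 0.133 within a spike-in class (110 pairs). Between the classes it was -0.138 (105 pairs). The main fit, which gave the counts above, held no term for this class.

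For 4 against 2 weeks the counts were uncommon in NOD (129 and 136, 2 splits), NOR (1321 and 2147, 2 splits) and C57BL/6 (2204 and 2065, 1 split). The strain by age interaction count was uncommon as well (18 and 5, 1 split). The count for the age change in NOD minus that in C57BL/6 was not uncommon (9, with 7 splits as large and up to 1226). For NOD minus NOR the count was 0 by limma, so all 100 splits are as large by construction (up to 494) and nothing about chance was tested. The number of lists called was as large in 49 splits for NOD against NOR (12, up to 30), 36 for NOD against C57BL/6 (13, up to 28) and 30 for NOR against C57BL/6 (13, up to 26). It was as large in 27 for the age change in NOD (13, up to 21) and 5 in C57BL/6 (26, up to 28). These numbers were not uncommon. The number for the age change in NOR was uncommon (28, with 4 splits as large and up to 31). For the type I interferon list itself the real split alone gave a median as large, against NOR (highest other 0.198) and against C57BL/6 (0.356). The same held for the erythroid (0.551) and cell cycle lists (0.375) against C57BL/6. It was not particular to these lists, since it also held for cytosolic ribosomal protein genes against NOR (0.178). For NOD against C57BL/6 it held too for the naive, Th17, cholesterol synthesis, T cell receptor signalling, MHC region and B cell lists.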
